A study of Ambystoma mexicanum with 4 samples.

How the data were processed

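The series holds 4 RNA-seq libraries of poly(A) RNA from axolotl tail tip, 2 from pools of copper animals and 2 from pools of their wild-type siblings. Per the labels' protocols, RNA was isolated with TRIzol, purified on columns with DNase treatment, and made into poly(A)-selected libraries by a sequencing company. The submitters' processing notes name HISAT2 2.2.0, SAMtools 1.19.2 and StringTie 2.2.1. Per the file headers, StringTie was run on each library with the AmexT_v47 gene annotation as a guide and only annotated transcripts were quantified. The gene identifiers carry the prefix AMEX60DD, and coordinates are those of the deposited files. The genome sequence itself was not used here, and a list of genes of another axolotl assembly, whose identifiers differ from those of the files, was not used.

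The deposited TPM values were made by the authors with StringTie and sum to the same total in each library, as transcripts per 1e+06 do. The deposited FPKM values are a constant multiple of TPM within a library. The deposited coverage is the mean read coverage per base of a transcript or exon, not scaled for depth. Read counts were not used here. Coverage times transcript length, divided by the read length of 150 bp that the values imply, gave whole numbers within 1 base for 6.64% to 7.50% of low transcripts, so whole reads could not be recovered. No test on read counts was run, and such read estimates entered only an alternative fit with limma-voom. Aligned sequence, from the ratio of coverage to FPKM, was 10.03 gigabases in copper pool 1, 7.27 in copper pool 2, 7.51 in wild-type pool 1 and 11.2 in wild-type pool 2, of which 85.2% to 86.9% lay in annotated genes. Any exact 0 in these values can be a failed estimate of StringTie as well as an absent transcript, and such genes are given as listed at 0.

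TPM was summed over the transcripts of a gene. The annotation held 99305 transcripts of 99088 genes, 99034 of them with a single transcript, and 40699 genes carried a name. Each of the 4 libraries was assigned to its group and replicate number from its title. Genes with a mean of at least 0.5 TPM over the 4 libraries were tested, 24429 in all. Log2(TPM + 1) values were compared with limma 3.58.1 in R 4.3.3 (empirical Bayes moderation with an intensity trend, two-sided, no replicate block), with Benjamini-Hochberg adjustment and a threshold of 0.05. Changes are therefore on the log2(TPM + 1) scale, which understates those of low genes. Folds are ratios of mean TPM, except that the fold of a list is taken from its median log2 change, and are not given where a group is listed at 0. Values were read with the R package data.table (version 1.17.8) and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

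The 15 gene lists were written from general knowledge of pigment cells and of the tissues of a tail: melanin synthesis and melanosome proteins, melanophore lineage regulators, melanosome biogenesis and transport, xanthophores, iridophores, epidermis, skeletal muscle, connective tissue with cartilage and notochord, nervous tissue and glia, red blood cells, immune cells, endoplasmic reticulum stress, oxidative stress, cell cycle, and immediate early genes. A symbol with several loci was represented by the locus with the highest mean TPM. Lists were tested with camera at its preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the 15 lists. Members were also adjusted over the list alone. With an estimated correlation, camera also refers its statistic to the residual degrees of freedom of the 4 libraries. That form therefore had little power, and a call lost there cannot be put down to correlation alone. Genes starting within 100 Mb of TYRP1, TYRP1 left out, were compared with all other tested genes by Fisher's exact test on the share with an unadjusted p under 0.05, as fixed for the case of fewer than 20 changed genes. Exon coverage of TYRP1 was divided by the library's coverage per TPM and not tested.

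Genes named in the text were chosen by a rule. It took every TYRP1 locus and every tested melanin gene. It took the named genes with the smallest p and no overlap between groups (10 in each direction, or 5 where fewer than 5 pass). It also took up to 4 members of each other list with the smallest unadjusted p, and up to 5 changed genes near TYRP1, of which there were none. Some genes that this rule selects are not reported here. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, except where a choice is said to have been made later. SOX10, KIT and MITF, H355_002137, LOC115374818, MTAP, MYH1 and the unnamed genes were named outside the rule, after their values were seen.

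The alternatives were pseudocounts of 0.1 and 0.5, no filter or a filter at 5 TPM, median-ratio scaling, quantile normalization, FPKM, limma without the intensity trend, limma-voom on read estimates, a replicate block, each replicate left out in turn, an adjusted p under 0.1, TPM summed over loci of a symbol, windows of 50 Mb, 300 Mb or the whole arm around TYRP1, unscaled exon coverage, and lists with all loci kept. With a replicate left out, the lone pool of a group was assumed to vary like the other group. In the limma-voom setting, lists were tested with camera on the log values of voom, without its weights or an intensity trend. The limma step was tested on simulated data for copper against wild type over 24429 genes, with the means and spread of the real genes and 200 changed genes of at least moderate level per run. It recovered 0% of genes changed by 0.5 on the log2 scale, 58.5% of those changed by 1 and 85.5% of those changed by 2, with 0, 2 and 9 false calls. A run without changed genes gave 0 calls. Genes were simulated as independent, without effects shared by the genes of a pool, so these runs do not show how many false calls real pools give. Other divisions of the 4 real libraries into 2 and 2 gave 4 and 9 genes past the threshold (limma).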

Results

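Poly(A)-selected RNA was sequenced from the tail tip of axolotls (Ambystoma mexicanum), a salamander bred in laboratories for work on regeneration and pigmentation. Copper is an inherited colour mutant of this species. The 4 libraries came from 2 pools of copper animals and 2 pools of siblings with wild-type coloration. The siblings shared a copper father, homozygous for the mutation, and a heterozygous mother, so a wild-type animal of this cross is expected to carry 1 wild-type copy and 1 copper copy. How many animals made up a pool is not given in the sources used here. P-values of limma measure the spread between pools. Fisher's exact test takes genes as units. Camera at its preset correlation treats genes as nearly independent, though all come from the same 4 pools. The copper libraries held 10.03 and 7.27 gigabases of aligned sequence and the wild-type libraries 7.51 and 11.2 gigabases. Between 20214 and 20596 genes per library reached 1 TPM, the abundance unit of the deposited values. Log2 levels correlated across genes at Pearson's r of 0.984 to 0.988 between any 2 libraries, and the 2 copper libraries, at 0.984, were no closer to each other than to wild type. Genes are not independent replicates in these correlations. Copper pool 2 stood apart from the other 3 libraries on the first principal component, which held 41.3% of the variance.

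The study's title names TYRP1 as the gene behind the copper phenotype, and its level in each library was examined first. TYRP1 encodes tyrosinase-related protein 1, a melanosomal enzyme of eumelanin synthesis. The annotation held a single locus of this name, AMEX60DD043361, with 8 exons on the plus strand of 6p from 1225534073 to 1225543009. TYRP1 was measured at 9.34 and 8.75 TPM in the copper pools and at 43.2 and 39.0 TPM in the wild-type pools. The group means were 9.04 ± 0.420 TPM in copper and 41.1 ± 2.96 TPM in wild type (SD, n = 2 pools), a 4.54-fold lower level in copper. On the log2(TPM + 1) scale TYRP1 fell by 2.07 (SE 0.0847), and the change passed the threshold over 24429 genes (limma, adjusted p = 0.0463). Of all genes tested, TYRP1 had the second smallest p. With any single pool left out, the log2 change stayed between -2.14 and -1.99 but did not pass the threshold (limma, adjusted p from 0.0929 to 0.338). The call was also lost with a pseudocount of 0.1 (limma, adjusted p = 0.0774), without the filter on low levels (adjusted p = 0.265) and without the intensity trend (adjusted p = 0.131). Divisions of the libraries that mixed the groups reached smallest adjusted p of 0.000117 and 0.000261 (limma), so 0.0463 is not a calibrated call.

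TYRP1 transcripts in copper pools covered every annotated exon. After division by each library's coverage per TPM, mean coverage of exon 2 (1225534916 to 1225535355) was 15.0 and 12.9 in the copper pools and 80.1 and 64.9 in the wild-type pools. The ratio of copper to wild type was lowest in exon 1 (0.178) and highest in exon 7 (0.270), with a median of 0.226 over the 8 exons. Both copper pools lay below both wild-type pools in each exon. Exon 1, at the 5' end, was thinly covered in both groups, with 0.668 on average in copper and 3.76 in wild type. Exon coverage was compared without a test, since an exact two-sided test of 2 pools against 2 cannot give a p below 0.333.

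**Figure D1:**
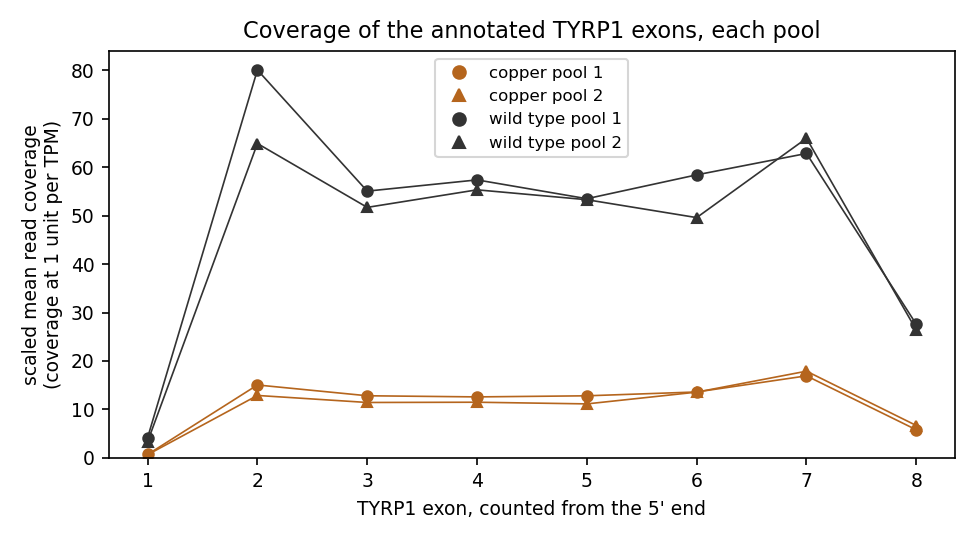
Mean read coverage of each annotated TYRP1 exon, divided by the library's coverage per TPM, against exon number from the 5' end, with a line and a marker for each pool. Both copper pools lie below both wild-type pools in all 8 exons, with copper to wild-type ratios of 0.178 to 0.270.

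The other genes of melanin synthesis did not share the lower level of TYRP1. Of the 12 other tested members of the list of melanin and melanosome genes, 10 had higher mean log2 levels in copper, and in 8 of them the pools of the groups did not overlap, against 39.8% of all genes tested and 33.3% by chance, in either direction. Their median difference was 0.31 on the log2 scale, or 1.24-fold. PMEL, which forms the fibrils on which melanin is laid down, had 269 ± 9.14 TPM in copper and 211 ± 28.7 TPM in wild type (SD, n = 2). DCT, the dopachrome tautomerase, had 137 ± 7.93 and 109 ± 6.06 TPM, and MLANA, a melanosomal membrane protein, had 73.4 ± 6.66 and 52.4 ± 1.58 TPM. OCA2, an anion transporter of the melanosome, had 11.2 ± 1.20 TPM in copper and 7.36 ± 0.526 TPM in wild type. TYR, the tyrosinase that starts melanin synthesis, had 43.1 ± 5.15 and 35.4 ± 1.20 TPM. GPNMB (162 ± 17.5 against 122 ± 19.8 TPM) and SLC24A5 (12.9 ± 2.26 against 9.54 ± 1.08 TPM) also differed without overlap, as did GPR143 (26.8 ± 0.968 against 24.1 ± 0.0783 TPM). CD63, TPCN2, TRPM1 and SLC45A2 overlapped between the groups. The log2 differences of CD63, TPCN2 and TRPM1 lay between -0.06 and 0.01.

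None of these 12 genes passed the threshold over all genes tested. Adjusted over the list alone, MLANA, OCA2 and DCT rose and TYRP1 fell (limma, adjusted p under 0.05 within the list of 13 tested members). MLANA lies 43.5 Mb from TYRP1 on 6p and is counted again below among the genes near TYRP1. As a list the melanin genes rose relative to other genes (camera with a preset correlation of 0.01, adjusted p = 8.3e-05 over 15 lists). The call did not pass with an estimated correlation (camera, adjusted p = 0.874), a form of the test with little power on 4 libraries. A test of whether the members share a direction on balance did not pass (fry, adjusted p = 0.922). The test for change in either direction did, with TYRP1 among the members (fry, mixed adjusted p = 0.00256). Without TYRP1, a choice made after the data were seen, camera gave p = 4.33e-09 for the 12 genes at the preset correlation. That p treats the genes as nearly independent. With their estimated correlation, 0.746, camera gave p = 0.178.

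**Figure D2:**
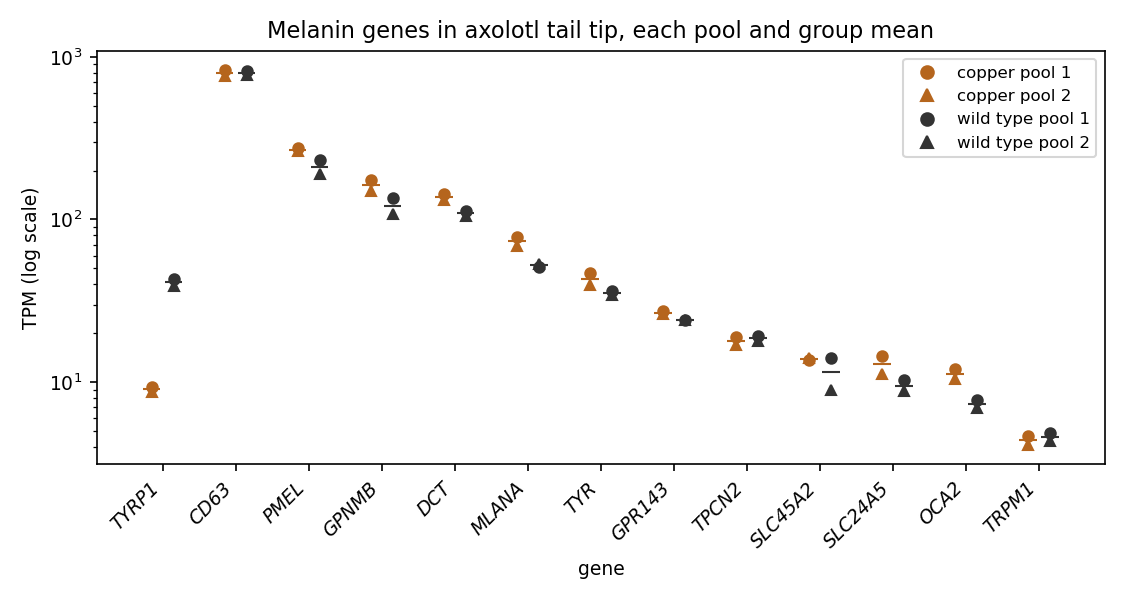
Level of each tested melanin gene in TPM on a log axis, with a marker for each pool and a bar at each group mean, TYRP1 first and the others by wild-type level. TYRP1 lies 4.54-fold lower in copper, while 10 of the other 12 genes have higher mean log2 levels in copper.

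Regulators of the melanophore lineage showed no common direction. Of 12 tested regulators, 6 were above 0 and 6 below, with a median log2 difference of -0.02 (camera, adjusted p = 0.931). SOX10, a transcription factor of neural crest derivatives, had 11.9 ± 0.0135 TPM in copper and 11.6 ± 0.420 TPM in wild type. KIT, a receptor needed by melanophore precursors, had 5.50 ± 0.0481 and 5.71 ± 0.507 TPM, and MITF, the regulator of melanocyte genes, 1.73 ± 0.400 and 1.79 ± 0.0963 TPM. LEF1 (7.84 ± 0.0521 against 10.2 ± 1.74 TPM) and TFAP2B (13.5 ± 1.02 against 16.2 ± 0.177 TPM) had the smallest unadjusted p of the list, and neither passed over the list alone. Genes of melanosome biogenesis and transport did not differ as a list (25 tested, median -0.04, camera upward, adjusted p = 0.931), so that median and test differed in sign. RAB38, a small GTPase that directs cargo to melanosomes, had 26.5 ± 2.65 TPM in copper and 21.0 ± 0.981 TPM in wild type.

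In the list for xanthophores, the yellow pigment cells, 9 of 17 tested genes were above 0 and 8 below. The median was 0.01 and the mean -0.04 on the log2 scale (camera upward, adjusted p = 0.931; fry downward, adjusted p = 0.108). PTS, which catalyses a step of tetrahydrobiopterin and pteridine synthesis, had 85.0 ± 4.52 TPM in copper and 111 ± 0.340 TPM in wild type. PTS fell when adjusted over the list alone and did not pass over all genes (limma, log2 -0.38, adjusted p = 0.751). XDH, xanthine dehydrogenase, had 3.67 ± 0.616 and 4.58 ± 0.151 TPM. The list for iridophores, the reflecting pigment cells, had a median of -0.04 over 18 genes (camera, adjusted p = 0.604). The test for change in either direction passed for this list (fry, mixed adjusted p = 0.0315), though 17 of the 18 members had an unadjusted p of at least 0.05. ADSS2, an enzyme of AMP synthesis, had 14.1 ± 0.340 TPM in copper and 18.2 ± 0.565 TPM in wild type, and did not pass over the list alone.

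Among the lists for other tissues of the tail, epidermal genes fell relative to other genes. Of 24 tested, 21 were below 0, with a median of -0.14 (camera, adjusted p = 0.000331; adjusted p = 0.839 with an estimated correlation). PKP3, a desmosomal plaque protein, had 21.9 ± 0.635 TPM in copper and 28.2 ± 0.991 TPM in wild type, and the keratin KRT15 had 2053 ± 226 and 2494 ± 90.1 TPM. Genes of connective tissue, cartilage and notochord also fell as a list, with 18 of 20 below 0 and a median of -0.12 (camera, adjusted p = 0.0009; adjusted p = 0.839 with an estimated correlation). COL2A1, the main collagen of cartilage, had 2457 ± 106 TPM in copper and 2918 ± 159 TPM in wild type, and COL11A1 had 684 ± 15.1 and 786 ± 11.9 TPM. Of all genes tested, 63.3% were below 0, and their median was itself -0.05. With median-ratio scaling the medians of these lists were -0.08 and -0.07. Without copper pool 2 the epidermal median was -0.07. Both calls were lost on the log values of voom without its weights (camera, adjusted p = 0.0538 for each). Cell cycle genes fell as a list in the test with the preset correlation (21 of 23 below 0, median -0.12, camera, adjusted p = 0.0319; adjusted p = 0.932 with an estimated correlation). TOP2A, a topoisomerase of dividing cells, had 122 ± 6.37 and 148 ± 12.7 TPM. The cell cycle call was lost with median-ratio scaling (camera, adjusted p = 0.214), FPKM (0.0638) and a minimum of 5 TPM (0.103). It was also lost with no intensity trend (camera, adjusted p = 0.0987) and on the unweighted log values of voom (0.309). Without copper pool 2 the cell cycle median was -0.06. Its median ranged from -0.22 without wild-type pool 2 to -0.02 without wild-type pool 1. The test for a common direction did not pass for epidermis (fry, adjusted p = 0.266), connective tissue (0.108) or cell cycle (0.907). The test for change in either direction passed for connective tissue alone of these lists (fry, mixed adjusted p = 0.0252). No member of these 3 lists passed over all genes or adjusted over the list alone.

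The remaining lists did not pass. Genes of nervous tissue and glia had 17 of 18 members below 0, against 63.3% of all genes, and a median of -0.12 (camera, adjusted p = 0.0845). The myelin gene MBP had 53.0 ± 13.1 TPM in copper and 74.9 ± 8.75 TPM in wild type. Skeletal muscle genes had a median of -0.11 over 26 genes (camera, adjusted p = 0.123), and passed as lower with quantile normalization (0.0205) and with all loci kept (0.0251). Without copper pool 2 the medians were -0.24 for nervous tissue and -0.25 for muscle. Without copper pool 1 they were -0.01 and 0.06, and both lists turned upward relative to other genes. There, 20 of 26 muscle genes were above 0, and 8 of 18 nervous tissue genes. Without wild-type pool 1 the nervous tissue median was -0.19. The members of a list are not independent, with estimated correlations of 0.575 for nervous tissue and 0.678 for muscle. Red blood cell genes had a median of 0.03 and a mean of 0.23 over 12 genes (camera, adjusted p = 0.101), with the globin HBE1 at 105 ± 21.9 TPM in copper and 49.6 ± 27.6 TPM in wild type. Without wild-type pool 1 the median of this list was 0.41. Without wild-type pool 2 it was -0.18, with 9 of 12 genes below 0. The estimated correlation between these genes was 0.708. Oxidative stress genes had a median of 0.05 over 16 genes (camera, adjusted p = 0.0539), with GCLM, a subunit of the enzyme that starts glutathione synthesis, at 140 ± 16.2 and 111 ± 2.53 TPM. The list passed as higher with median-ratio scaling, FPKM, a minimum of 5 TPM or all loci kept, and without copper pool 2 or wild-type pool 1 (camera, adjusted p from 0.000312 to 0.0398). It did not pass without copper pool 1 (median 0.01; camera, adjusted p = 0.33) or wild-type pool 2 (median 0.00, 8 of 16 genes above 0; adjusted p = 0.329). Immediate early and wounding genes had a median of 0.00 over 23 genes (camera upward, adjusted p = 0.0845), and JUNB had 38.6 ± 0.434 and 32.3 ± 2.84 TPM. That list passed as higher with median-ratio scaling (camera, adjusted p = 0.0361), with all loci kept (0.0251) and without copper pool 2 (0.0205), where the median was 0.09. Without copper pool 1 the median was -0.04, with 8 genes above 0 and 15 below (camera, adjusted p = 0.617). Immune cell genes had a median of 0.03 and a mean of -0.01 over 17 genes (camera, adjusted p = 0.338). Of 22 genes of the endoplasmic reticulum stress response, 15 were below 0, near the share of 63.3% over all genes. None reached an unadjusted p under 0.05, and the median was -0.05 (camera, adjusted p = 0.931). With median-ratio scaling, 15 were above 0 and 7 below, with a median of 0.009. No member of these 7 lists passed over all genes or adjusted over the list alone.

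**Figure D3:**
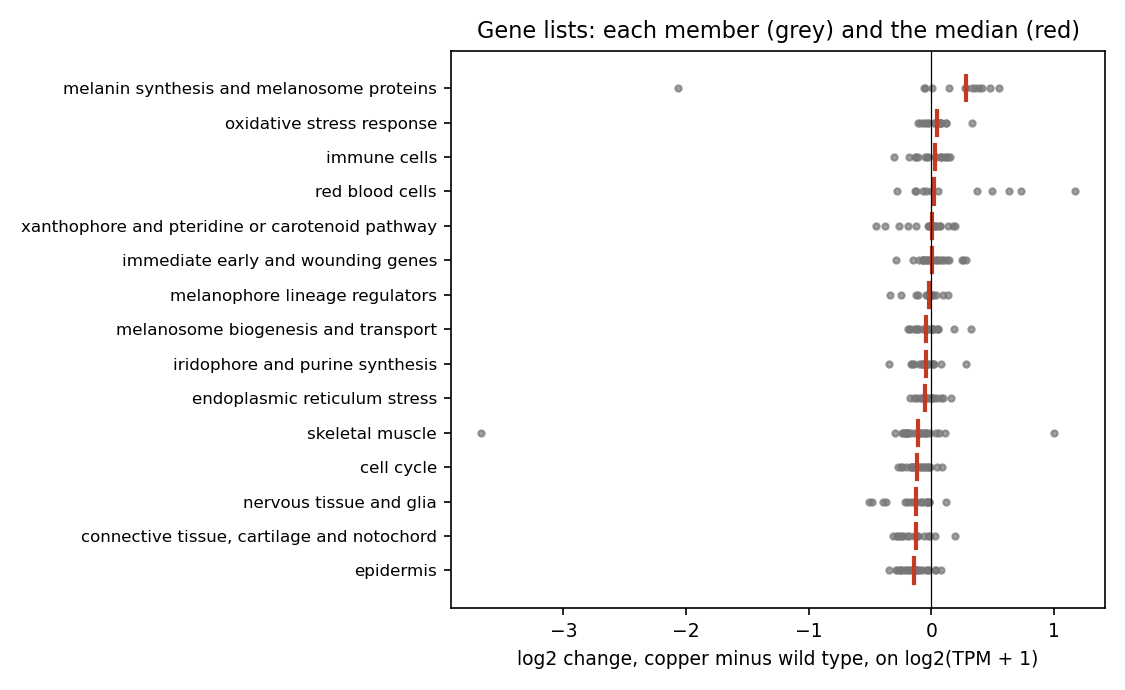
Log2 change between copper and wild type on the log2(TPM + 1) scale for each tested member of the 15 gene lists (grey points) with the median of each list (red bar). The melanin list has the highest median, 0.28 with TYRP1 included, and epidermis the lowest, -0.14.

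Over the whole transcriptome, 2 of 24429 genes changed between copper and wild type (limma, adjusted p = 0.0463 for both). Beside TYRP1 this was AMEX60DD029171, an unnamed gene on the minus strand of 3q from 292692494 to 292697712. It was measured at 7.95 and 8.16 TPM in the copper pools and was listed at 0 in both wild-type pools. It lies almost wholly over AMEX60DD029170 on the plus strand, listed at 0 in all 4 libraries, and the strandedness of the libraries is not given in the sources used here. An unadjusted p under 0.05 was reached by 1586 genes, 570 higher and 1016 lower in copper. By chance 1221 are expected, and 1374 (5.62%) reached it in simulated data without change. Genes were simulated as independent, and real divisions that mixed the groups gave 898 and 1019. Whether 1586 is an excess therefore cannot be told. With median-ratio scaling, 61.1% of genes at an unadjusted p under 0.05 were higher in copper, against 35.9% in the values as deposited. No gene passed without copper pool 2 or without wild-type pool 2, 1 passed without copper pool 1, and 4 passed without wild-type pool 1. The genes that passed in those fits did not include TYRP1 or AMEX60DD029171.

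Apart from TYRP1, the named genes with the smallest p did not pass the threshold, and several were listed at 0 in a whole group. H355_002137 on 1p was listed at 0 in both copper pools and at 4.86 and 5.31 TPM in wild type (limma, adjusted p = 0.0742), and it passed when TPM was summed over loci of a symbol, where 3 genes did. TRIM39 (AMEX60DD010570, 13q) was listed at 4.13 TPM in both copper pools and at 0 in wild type (limma, adjusted p = 0.0851), and C5ORF63 on 6p at 5.24 and 3.94 TPM and at 0. TRIM39 is a name carried by many loci, of which AMEX60DD010571 overlaps it on the other strand. SCAPER was listed at 1.13 and 1.73 TPM in copper and at 0 in wild type, and ELMOD1 at 0 in both copper pools and at 1.191 and 1.60 TPM in wild type. MTX3, a mitochondrial import protein on 6p, had 2.57 ± 0.0812 TPM in copper and 0.188 ± 0.0289 TPM in wild type (limma, adjusted p = 0.352). Its antisense neighbour LOC115374818 was listed at 0 in both copper pools and at 2.90 and 2.80 TPM in wild type, and without strand the reads of the pair cannot be told apart. Both passed with limma-voom on read estimates (adjusted p = 0.0182 for MTX3 and 0.0342 for LOC115374818). A value of 0 was not always shared by a group. A MYH1 locus on 2p, a muscle myosin heavy chain chosen after its values were seen, was listed at 0 in copper pool 2 and at 125 to 154 TPM in the other libraries. The ribosomal protein gene RPL18 had 1244 ± 10.9 TPM in copper and 902 ± 75.9 TPM in wild type at the locus AMEX60DD038449. A more abundant RPL18 locus, AMEX60DD016566, had 1647 ± 48.8 and 1621 ± 101 TPM. On the lower side, the phosphatase gene PTPRB had 5.36 ± 0.114 TPM in copper and 10.5 ± 0.980 TPM in wild type. TMEM215 had 29.9 ± 2.09 and 47.9 ± 3.005 TPM. The adjusted p was 0.751 for TMEM215, PTPRB and RPL18 at AMEX60DD038449, and 0.928 for RPL18 at AMEX60DD016566 (limma).

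Because copper and wild-type siblings differ in genotype around the causal locus, genes near TYRP1 were compared with all others. Within 100 Mb of TYRP1 on 6p, 10 of 102 tested genes (9.80%) had an unadjusted p under 0.05, 4 higher and 6 lower in copper, against 6.47% of 24326 other genes. The odds ratio was 1.57 (95% confidence interval 0.73 to 3.03) and the difference did not pass a two-sided Fisher's exact test (p = 0.16). None of the 102 genes passed over all genes tested. Fisher's exact test takes genes as units, and neighbouring genes of the same pools are not independent. At an unadjusted p under 0.01, a threshold chosen after the data were seen, the count was 5 of 102 (4.90%) against 1.07% elsewhere, an odds ratio of 4.75 (95% confidence interval 1.497 to 11.6; Fisher's exact test, p = 0.00521). The 5 genes were MLANA, 43.5 Mb from TYRP1, MTAP (36.9 ± 1.94 against 29.6 ± 0.676 TPM) and the unnamed AMEX60DD043325 (16.9 ± 0.0785 against 9.65 ± 0.463 TPM), all with higher values in copper, and TMEM215 and the unnamed AMEX60DD043428 (1.48 ± 0.907 against 4.89 ± 0.804 TPM) with lower values. At a p under 0.05 the difference did pass without the intensity trend (odds ratio 2.56; Fisher's exact test, p = 0.00261), without the filter (1.98; p = 0.00663), with limma-voom on read estimates (2.22; p = 0.0156) and over the whole arm (1.27; p = 0.0439). Without copper pool 2 the odds ratio was 3.07 (Fisher's exact test, p = 0.000234), and without copper pool 1 it was 1.88 (p = 0.0349). It did not pass Fisher's exact test without wild-type pool 1 (1.42; p = 0.33) or wild-type pool 2 (1.505; p = 0.265), within 50 Mb (2.02; p = 0.0964) or 300 Mb (1.18; p = 0.388), or with median-ratio scaling (1.41; p = 0.308).

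**Figure D4:**
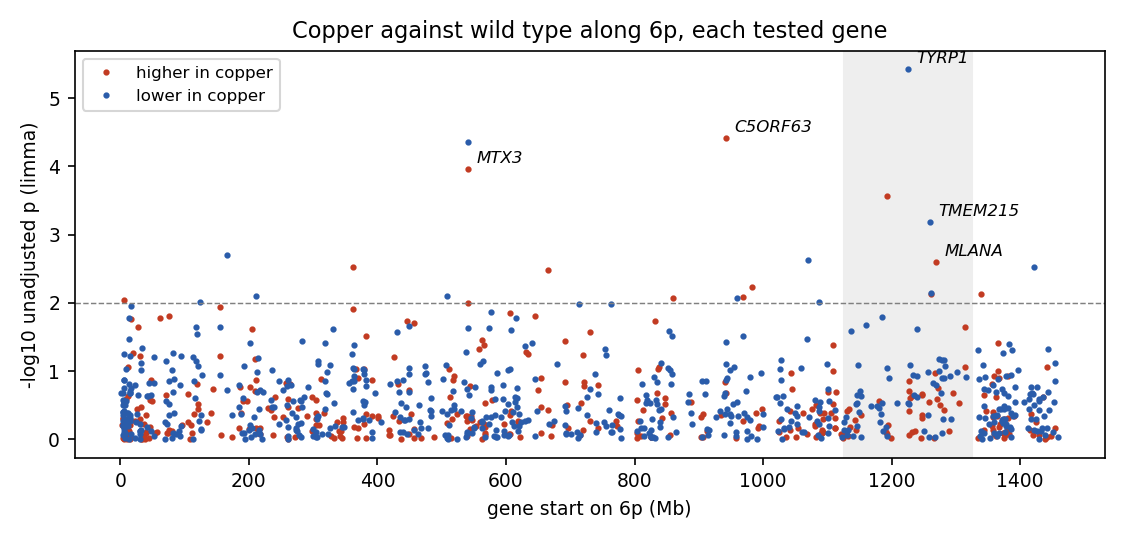
The -log10 of the unadjusted limma p of each tested gene on 6p against the start of the gene in Mb, coloured by direction, with the 100 Mb on each side of TYRP1 shaded and a dashed line at 0.01. TYRP1 has the smallest p of the arm, and 5 of the other 102 genes in the shaded part lie above the line.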

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

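The count near TYRP1 at a p under 0.01 and the melanin list without TYRP1 were chosen after the data were seen. The lower level of TYRP1 kept its direction in every setting run, from -2.17 to -1.90 on the log2 scale (limma, adjusted p from 0.0104 to 0.388). It did not pass with a pseudocount of 0.1 (log2 change -2.17), nor without the filter, without the intensity trend or with a replicate block, which left its value at -2.07. It passed in no fit with a replicate left out (-2.14 to -1.99), where fewer libraries were available. Without the filter 52806 genes entered the adjustment. The exon ratio was 0.214 unscaled and 0.211 to 0.232 with a replicate left out, where dropping copper replicate 1 moved it by more than the spread between pairs of pools, 0.0124. The number of changed genes was 0 with a pseudocount of 0.1 and 0 without the filter (limma; 1558 and 2803 genes at an unadjusted p under 0.05). It was 1 at a minimum of 5 TPM, 1 without the intensity trend, 5 with voom and 4 at an adjusted p under 0.1, and 0 to 4 with a replicate left out. Both genes passed with a pseudocount of 0.5, median-ratio scaling, quantile normalization, FPKM and voom. The number of lists past the threshold was 4 in the settings as fixed and 7 with all loci kept. It was 1 on the log values of voom without its weights (the melanin list). With an estimated correlation it was 0, where the test had little power. There, even immediate early genes, at an estimated correlation of 0.0132, went from p = 0.0394 to p = 0.183 (camera, unadjusted). The odds ratio near TYRP1 stayed above 1 in every setting run and passed Fisher's exact test without the filter (1.98), without the intensity trend (2.56), with voom (2.22), over the whole arm (1.27) and at a p under 0.01 (4.75), and its range was 1.42 to 3.07 with a replicate left out. The cause was not tested for these differences.

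The replicate numbers are not stated to pair the pools, and deviations of libraries with the same number were uncorrelated across genes (r = -0.0333). With the replicate block, 0 genes passed (limma, 1498 at an unadjusted p under 0.05) and TYRP1 was at -2.07 (adjusted p = 0.388). There, 7 lists passed. Those gained were nervous tissue as lower (camera, adjusted p = 0.00406), and oxidative stress (0.0415) and red blood cells (0.0456) as higher. The odds ratio near TYRP1 was 1.86 (Fisher's exact test, p = 0.0598). The block leaves a single residual degree of freedom per gene before moderation.

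Some lists that did not pass in the settings as fixed turned direction elsewhere, at these camera adjusted p. For lists, voom means its log values without its weights. Endoplasmic reticulum stress turned at a minimum of 5 TPM (0.829), with median-ratio scaling (0.220), FPKM (0.822), no intensity trend (0.919), voom (0.485) and all loci kept (0.689). Melanophore regulators turned at 5 TPM (0.831), with median-ratio scaling (0.769), quantile normalization (0.674), FPKM (0.911), voom (0.854) and all loci (0.811). The iridophore list turned with median-ratio scaling (0.769), voom (0.933) and all loci (0.853), the melanosome transport list without the filter (0.763) and with all loci (0.513), and the xanthophore list without the filter (0.763) and with all loci (0.853). With a replicate left out the direction turned at least once, over ranges of 0.219 to 0.843 for endoplasmic reticulum stress, 0.0736 to 0.914 for immune cells, 0.257 to 0.908 for iridophores, 0.552 to 0.993 for melanophore regulators, 0.132 to 0.908 for melanosome transport, 2.38e-05 to 0.617 for nervous tissue, 1.28e-07 to 0.552 for red blood cells, 3.94e-12 to 0.329 for muscle and 0.803 to 0.993 for xanthophores. Of the named genes, KIT turned to a log2 change of 0.0063 with median-ratio scaling, 0.016 with quantile normalization and 0.0087 with voom, where TRPM1 was at 0.0043 and MITF at 0.018. With a replicate left out, log2 changes crossed 0 for CD63 (-0.054 to 0.074), KIT (-0.12 to 0.035), MITF (-0.19 to 0.11), SLC45A2 (-0.021 to 0.58), TPCN2 (-0.13 to 0.013) and TRPM1 (-0.13 to 0.025). The cause was not tested. Of the values of named genes other than TYRP1 over all settings, 1172 kept direction and side of the threshold. Another 13 turned direction, 7 lost the threshold and 3 gained it. Of these genes only AMEX60DD029171 passed in the settings as fixed. Most kept values are thus of genes that stayed short of the threshold, which says little about their stability. The counting error of single genes was not computed, and read estimates from coverage entered only the voom fit.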

Other observations

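The tests on genes near TYRP1 at a p under 0.01, the window scans, the alignment test, the melanophore markers, the test of single pools on the melanin genes and the choice of ribosomal protein genes as a group came after the data were seen. Genes for cytosolic ribosomal proteins, a group outside the fixed lists, had a higher level in copper at most of their loci. Of 200 tested loci, 172 were above 0, with a median log2 difference of 0.14, or 1.10-fold. At an unadjusted p under 0.05, 70 loci were higher and 3 lower, and none passed the threshold over all genes (limma). The median was positive under each scaling tried, from 0.13 with quantile normalization to 0.20 with median-ratio scaling.

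The small difference over ribosomal protein loci could come from several technical sources. Shorter transcripts tended upward in copper (Spearman's rho of log2 change with transcript length across genes, -0.157, genes not being independent). Random lists matched on length and mean TPM had a median of 0.02, and the ribosomal median lay above all 10000 of them (percentile 100, highest matched median 0.07). The lists drew genes independently, whereas many ribosomal loci share a gene name and are not independent. How closely the lists matched was not checked, so the percentile does not set this trend aside. The ribosomal difference did not rest on a single pool, since the smallest difference with a pool left out was 87.5% of the full one. Median-ratio scaling left 139% of the ribosomal median, but that scaling moved genes upward and could only enlarge a positive median. A difference that comes with the copper genotype was not tested and stays open, as does a difference in tissue makeup or RNA quality between the pools.

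The melanin genes other than TYRP1 had a mean log2 level of 5.63 and 5.47 in the copper pools and 5.37 and 5.21 in the wild-type pools. Median-ratio scaling left 118% of their median difference. The median over all genes was -0.05 as deposited, so this scaling moved genes upward and could only enlarge a positive median. A common upward shift of all genes in copper was not seen, but the check cannot decide on other effects of scaling. Whether the copper pools held a larger share of melanophores cannot be told. The median log2 change of MITF, SOX10 and KIT lay at -0.344 relative to that of the 12 genes, and at -0.346 without SOX10, which also marks glia. These markers were chosen after MITF and KIT had been seen, and MITF is near the floor, at 1.73 TPM in copper, so the gap decides nothing. Whether a single pool sets the size of the difference cannot be told apart from a difference between groups with 2 pools each: it kept 68.3% of its value in the least favourable case, without wild-type pool 2. A change of these genes within the melanophores of copper animals is a hypothesis that was not tested.

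Near TYRP1, 4.90% of genes had an unadjusted p under 0.01. Chance clustering along the genome stays open. Of 140 other windows of 200 Mb with at least 50 tested genes, 1 (0.714%) held as large a share (on 1q, 4.94%). Windows on 13p (4.59%), 6p from 800 to 1000 Mb (4.24%) and 7q (4.10%) held 5 such genes each. Windows on 6p may be inherited together with TYRP1 in this cross, so they are not a clean comparison. With TYRP1 included, 6p ranked 1 of 28 arms at this threshold (24 of 1021 genes, 2.35%) and 2 at a p under 0.05 (8.13%). At the planned p under 0.05 the share near TYRP1 was 9.80%, and 12 of the 140 windows (8.57%) held as large a share. Poorer alignment of reads from the copper haplotype might lower genes there, but 40% of the 5 genes were lower in copper, and 5 genes are too few to decide. Variants linked to the copper allele that act on nearby genes are a biological hypothesis that the design allows and that was not tested.

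The 4 libraries can be divided into 2 and 2 in 3 ways, so no share under 0.05 can be reached. The real division gave 2 genes past the threshold, and all 3 divisions gave at least as many, the highest of the others 9 (limma). The smallest adjusted p was 0.0463 in the real division and 0.000117 and 0.000261 in the others (limma). At an unadjusted p under 0.05 the real division gave 1586 genes and the others 898 and 1019. Genes listed at 0 in both pools of one side and above 0 in both of the other numbered 23 in the real division and 19 and 26 in the others.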
